A study of Mus musculus with 2 samples.

How the data were processed

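Dispersed pituitary cells of male C57BL/6 mice aged 7 weeks were profiled with the 10x Genomics 3' droplet chemistry. Per the labels' protocols, 2 pools of 3 glands were digested for 4 h, cell viability was 71 to 82%, and 17400 cells were loaded per pool with 10000 targeted and a multiplet rate of 7.6%. The deposited matrix holds raw UMI counts, made by the authors with Cell Ranger and STAR against mm10, per the submitters' processing notes, whose versions are not given in the sources used here. Whether the depth of the libraries was made equal when they were combined is not given there either, so totals and medians per library are those of the deposited matrix. It lists 28693 genes and 13663 barcodes, and the number at the end of each barcode was taken as the number of the pool. A total of 58 gene symbols that occur more than once were kept apart by identifier. Gene positions come from the GENCODE annotation of the same assembly.

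Barcodes were kept with at least 500 UMIs, at least 250 genes and at most 20% mitochondrial UMIs, which left 6505 of 6546 in library 1 and 7060 of 7117 in library 2. There were 24 and 21 barcodes under the gene minimum and 17 and 36 above the mitochondrial maximum. Scrublet's own threshold called 2 and 6 cells, under the planned minimum of 0.5%, so the planned fallback removed the 7.6% of cells with the highest scores, 494 and 537. This left 6011 and 6523 cells. Cells were clustered on 91 marker genes fixed before the data were examined, as log1p of counts scaled to 10000 per cell and scaled per gene up to 10, with 12 principal components, 15 exact nearest neighbours weighted as in UMAP, and Leiden at resolution 1. The number of components came from parallel analysis with 20 permutations. A class was named "X-like" from at least 3 of its markers with a log2 level above the midpoint between the lowest and the highest cluster. A cluster stayed unnamed if another class had more markers among its 10 leading genes, or if it was shallow and had none of its own there. The rule for components, the limits for mixed clusters (between 20% and 90% high-Gh cells, with cycling clusters exempt), for high Gh (over 30% of UMIs) and high Prl (over 15%), and the exact neighbours, taken so that the result does not depend on the computer, were set after the data were seen. Clustering on 2000 variable genes without the markers gave the same class for 96.3% of 11513 named cells, 11088 in all (adjusted Rand index 0.92).

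Raw counts were summed per class and library, since cells are not replicates, and tested with edgeR's quasi-likelihood test (robust, TMM scaling, filterByExpr on class, library as a block) with Benjamini-Hochberg adjustment at 0.05. Classes with at least 20 cells in each library entered 1 fit of 22 columns, with 12166 genes tested, 75 marker genes left out, 10 residual degrees of freedom and a common biological coefficient of variation of 0.0638. The fit with thyrotrope-like cells added, at least 10 cells per library, had 24 columns, 12270 genes, 76 markers left out, 11 degrees of freedom and a coefficient of 0.0639. Each hormone class was compared with the equally weighted mean of the other hormone classes, stem-like and cycling cells with the mean of the hormone classes, and the remaining classes with the mean of all others. CPM are per-million values of the TMM-scaled total, and a transcript that dominates a class, such as Gh, can exceed that total. Folds given without a log2 value are ratios of mean CPM. A log2 fold change against several classes uses the mean of their log2 levels, so the 2 measures can differ. Against 0 UMIs a fold is a lower bound from 3 counts over the group. The count of genes at least 2-fold apart asks for at least 50 CPM on the higher side and a 2-fold difference of the mean, a definition changed after the data were seen. It uses no test, so these genes are not a part of those called. The first one asked for 2-fold in both libraries at any level and gave, for example, 3118 genes for stem-like cells.

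A set of 22 gene lists was fixed before the data were examined, as were the tests, the named-gene rule and most alternatives. Lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, with adjustment over 330 tests. Named genes passed the test in the same direction in both libraries, had at least 50 CPM on the higher side and were ranked by log2 fold change, leaving out predicted genes: the 12 highest and 8 lowest for stem-like cells, the 10 highest and 10 lowest for each pair of hormone classes, the 5 with the largest fold over the next hormone class for each hormone class, the 10 highest and 5 lowest for cycling cells and the 3 highest for each other class, plus list members and markers. Some genes that this rule takes are not reported here. Shares of cells with a UMI were taken after thinning each cell to 1000 UMIs and without thinning, with endothelial-like cells as the background. Intervals are exact binomial at 95% and cover counting error only.

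The tests were tried on simulated counts with known changes, in 200 genes for each comparison and in 1 list for the list test. The compared classes otherwise shared 1 profile. These counts therefore hold no difference in hormone share between the compared classes, and they do not bear on how the scaling moves the calls. For lactotrope-like against somatotrope-like cells (11996 genes) 2% of genes changed 1.5-fold were recovered, 34% of those changed 2-fold, 72% at 4-fold and 82% at 8-fold, with 0 false among 95 calls. For melanotrope-like against corticotrope-like cells (11952 genes) these were 4%, 24%, 60% and 74%, with 0 false among 81 calls, and for stem-like cells (11416 genes) 32%, 50%, 90% and 74%, with 1 false among 124. In the list test simulated for stem-like cells (12241 genes) the changed list was called and 1 of 20 unchanged lists was called too.

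Other settings tried were other normalizations (DESeq2 size factors, totals without hormone genes), DESeq2's Wald test, no filter, no block, each library left out, doublet calls kept, resolutions 0.5 and 2, clustering on variable genes, a minimum of 1500 UMIs, and 22 cells drawn per class and library. Added after the data were seen were another Leiden seed, the thyrotrope-like class, leaving out cells with over 30% Gh UMIs, and high-Gh cycling against somatotrope-like cells. Software was Python 3.11.15, scanpy 1.11.5, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.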

Results

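Pituitary glands of 7-week-old male mice of the inbred strain C57BL/6 were dispersed into single cells and profiled by droplet RNA sequencing, in which each captured transcript carries a unique molecular identifier (UMI). There were 2 libraries, each from a pool of 3 glands, and no second condition. Library 1 held 6546 barcodes with 70813117 UMIs, and library 2 held 7117 barcodes with 78861988 UMIs. The median barcode had 10128 UMIs and 2113 genes in library 1, and 10636 UMIs and 2153 genes in library 2. Gh, which encodes growth hormone, took 41.5% of all UMIs in library 1 and 38.3% in library 2, and Prl, which encodes prolactin, took 6.81% and 8.55%. The series set out to find genes that mark the stem cells and the hormone-producing classes of the gland, so the comparisons are between cell classes within the same glands. Levels are in CPM, counts scaled to a fixed total, as mean ± SD over the 2 libraries (n = 2). Log2 fold changes carry their standard errors, and adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. These p-values rest on how far 2 pools of glands disagree on the differences between classes, after the general difference between the pools is removed. This spread is shared over all classes in the fit and is not the spread between single animals.

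Somatotrope-like cells, the growth hormone class, made up 47.2 ± 2.42% of the cells used, and lactotrope-like cells, the prolactin class, 25.2 ± 2.32%. The somatotrope-like share was 36.3 ± 1.34% at a Leiden resolution of 0.5 and 36.6 ± 2.03% at a resolution of 2. It was 41.7 ± 1.82% with doublet calls kept and 50.6 ± 2.71% with clustering on variable genes. The SD between libraries does not cover this dependence on the clustering and on the naming of clusters. Gonadotrope-like cells made up 4.39 ± 0.0505% and corticotrope-like cells 3.57 ± 0.369%. Melanotrope-like cells of the intermediate lobe made up 1.93 ± 0.261%. Stem-like cells accounted for 2.87 ± 0.222% and cycling cells for 1.69 ± 0.176%. The cycling share leaves out a somatotrope-like cluster of 300 cells that had the cycling marker Cdk1 among its leading genes. Of its cells 96.3% had over 30% of their UMIs from Gh. At a Leiden resolution of 2 the stem-like share was 1.54 ± 0.0578%, and there a cluster of 167 cells with 5 stem cell markers had Lhb and Cga among its leading genes and stayed unnamed. Among classes without a pituitary hormone, endothelial-like cells made up 2.20 ± 0.0760%, fibroblast-like cells 1.25 ± 0.0744%, macrophage-like cells 1.10 ± 0.241% and pituicyte-like cells, the glia of the posterior lobe, 0.436 ± 0.0989%. The lactotrope-like share was 23.5% in library 1 (exact binomial 95% interval 22.5 to 24.6) and 26.8% in library 2 (25.8 to 27.9), and the somatotrope-like share was 48.9% (47.7 to 50.2) and 45.5% (44.3 to 46.7). For both classes the pools differed by more than counting error. Another 8.16 ± 0.573% of cells, in 5 of 30 clusters, stayed unnamed. Of these, 73.2% in library 1 and 60.5% in library 2 had over 30% of their UMIs from Gh. A rule on clusters that mix high-Gh and other cells, set after the data were seen, kept 3 of these clusters, 4.66% of cells in library 1 and 4.69% in library 2, out of a class. Another unnamed cluster, of 180 cells, was led by Pomc, with Egr4, Npas4 and Tnnt1 among its leading genes. It had only 2 markers of its best match, the somatotrope-like class, and the corticotrope-like share leaves it out. Thyrotrope-like cells formed no cluster of their own at the planned resolution. At resolution 2 they made up 10 cells in library 1 and 31 in library 2, or 0.321 ± 0.218%. A somatotrope-like cluster of 233 cells was led by Cd74 and class II antigen genes, yet only 9.01% of its cells held a Cd74 UMI, against 4.11% of the other somatotrope-like cells.

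**Figure D1:**
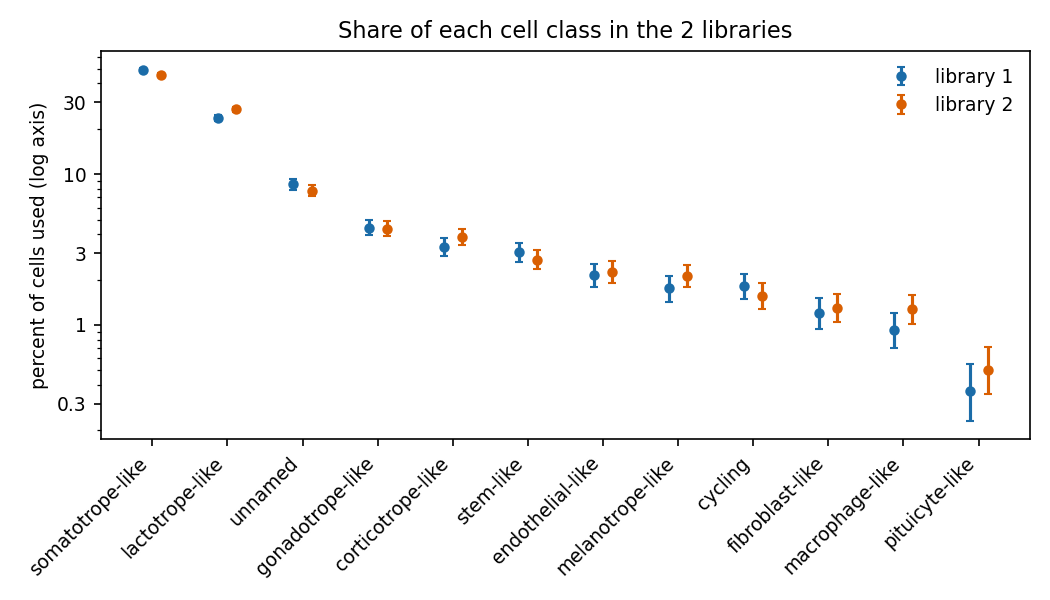
Percent of the cells used that fall in each class (log axis), per library, with exact binomial 95% intervals that cover counting error only. Shares run from 48.9% and 45.5% for somatotrope-like cells down to 0.366% and 0.506% for pituicyte-like cells.

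Hormone transcripts were found in every class, at levels that differed by orders of magnitude. Gh took a median of 62.0 ± 0.473% of the UMIs of a somatotrope-like cell and 1.04 ± 0.239% of those of an endothelial-like cell, which should lack it. Prl took 31.9 ± 2.37% in lactotrope-like cells and 0.272 ± 0.0360% in endothelial-like cells. With each cell thinned to 1000 UMIs, every endothelial-like cell still held a Gh UMI and 27.5 ± 0.537% held a UMI of Pomc, the precursor of corticotropin and melanotropin, against 99.3 ± 0.428% of corticotrope-like and 99.5 ± 0.673% of melanotrope-like cells. No cell used was shallower than 1000 UMIs. Lhb, the beta subunit of luteinizing hormone, was detected in 98.2 ± 0.0842% of gonadotrope-like, 15.9 ± 1.66% of stem-like and 4.95 ± 2.62% of endothelial-like cells at that depth. Fshb, the beta subunit of follicle-stimulating hormone, was detected in 89.4 ± 1.003%, 8.06 ± 1.81% and 0.340 ± 0.481% of the same classes. Without thinning, the median depths were 9029 UMIs in stem-like and 4538 in endothelial-like cells. There the Fshb shares were 16.1 ± 5.99% and 3.59 ± 0.694%, the Lhb shares 47.2 ± 11.7% and 26.3 ± 3.21%. Tshb, the beta subunit of thyrotropin, was seen in 2.62 ± 0.533% of somatotrope-like and 1.41 ± 0.895% of endothelial-like cells after thinning, and in 26.6 ± 2.20% and 7.71 ± 2.25% before it. The median depth of somatotrope-like cells was 13360 UMIs. Outside Gh and Prl it was 5051 ± 182 UMIs, against 4395.5 ± 179 in endothelial-like cells. Since Gh takes most UMIs of a somatotrope-like cell, thinning to a fixed total leaves that class fewer UMIs of other genes. The thinned Tshb shares of the 2 classes are therefore not at equal depth outside Gh. In CPM, Tshb stood at 49.5 ± 3.72 in somatotrope-like and 11.1 ± 3.21 in endothelial-like cells.

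Stem-like cells were compared with the mean of the 5 hormone classes to find the genes that mark them. Cyp2f2, a cytochrome P450 known from airway epithelium, reached 832 ± 12.1 CPM in stem-like cells against 2.90 CPM in the hormone classes (log2 fold change 8.45 ± 0.11, adjusted p = 4.95e-43). Aldh3a1, an aldehyde dehydrogenase gene, was at 165 ± 14.9 CPM against 0.541 (adjusted p = 1.05e-62), and Aldh1a2, which makes retinoic acid, at 374 ± 13.1 CPM against 3.63 (adjusted p = 4.34e-85). The lipoxygenase genes Alox15 and Alox12e were 203-fold and 107-fold higher in mean CPM, at 60.1 ± 11.4 and 70.2 ± 5.92 CPM. Also higher were the water and glycerol channel gene Aqp3 (132 ± 10.5 CPM, 238-fold), the carboxypeptidase family gene Cpxm2 (181 ± 6.23 CPM), and the tight junction gene Cldn10 (126 ± 11.8 CPM, 154-fold). Further ones were Tril (86.2 ± 12.4 CPM, 436-fold), Mlc1 (116 ± 17.3 CPM) and the endothelin receptor gene Ednrb (102 ± 11.2 CPM, 209-fold). Cldn10 was higher still in pituicyte-like cells, at 759.5 CPM, where Mlc1 was at 96.2 CPM, and Ednrb was at 72.1 CPM in endothelial-like cells. Among the lower genes, Calb1, which encodes a calcium-binding protein, was at 7.58 ± 4.16 CPM against 112 (−3.17 ± 0.20, adjusted p = 1.34e-16). Gpx3, which encodes a secreted glutathione peroxidase, was at 65.2 ± 21.1 CPM against 657.5 (−2.93 ± 0.10, adjusted p = 1.3e-44). Gria2, a glutamate receptor subunit gene, had a log2 fold change of −3.10 ± 0.23, and Caly, Necab2, Nap1l5, Tmem59l and Tmem130 lay between −2.92 and −2.81.

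Several of the named genes are close to each other in the genome (mm10). Cyp2f2 (27119909 to 27133660) and Cyp2t4 (27153714 to 27158668) are protein-coding genes of the same family on chromosome 7. Alox12e (70315610 to 70322628) and Alox15 (70344152 to 70352031) are both on chromosome 11, which also carries Aldh3a1 (61207537 to 61218421). Cyp2t4 was at 84.5 ± 16.2 CPM in stem-like cells, 408-fold over the hormone classes, but its adjusted p was 0.17 with DESeq2. How reads that match several related genes were counted is not given in the sources used here, so the values within each pair are uncertain.

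The fixed gene lists were tested between stem-like cells and the hormone classes. Where a list's call by camera was lost with an estimated correlation, that p is given beside it, and the other calls held. Of 25 measured secretory granule genes 22 were lower and 1 higher (24 and 1 adjusted over the list alone, camera adjusted p = 2.08e-11). Pcsk1n was at −2.71 ± 0.21, Snap25 at −2.68 ± 0.10 and Scg3 at −2.45 ± 0.17, while Cadps2 was higher by 1.01 ± 0.12. Epithelial genes were higher in 14 of 15 cases (14 adjusted over the list alone, camera adjusted p = 5.48e-08). Examples were the claudin gene Cldn7 (4.57 ± 0.12) and the keratin genes Krt18 (3.31 ± 0.07) and Krt8 (2.65 ± 0.15). Of 19 Notch genes 14 were higher and 1 lower (14 and 2 adjusted over the list alone, camera adjusted p = 5.94e-05). These included the receptor genes Notch1 (7.32 ± 0.36) and Notch3 (7.67 ± 0.42) and the target Hes1 (5.99 ± 0.24). All 16 genes past the test among 21 Wnt genes were higher (16 adjusted over the list alone, camera adjusted p = 1.94e-06). They included the secreted antagonist gene Sfrp5 (7.95 ± 0.23) and the repressor gene Tcf7l1 (5.37 ± 0.30). Hippo genes were higher in 15 of 16 cases (15 adjusted over the list alone, camera adjusted p = 3.23e-06). Yap1 was at 6.09 ± 0.22 and Wwtr1 at 4.14 ± 0.24. Of 24 genes of the BMP, FGF and TGF-beta list 20 were higher and 2 lower (20 and 2 adjusted over the list alone, camera adjusted p = 1.03e-07). Tgfb2 was at 7.01 ± 0.24 and Fgfr1 at 5.80 ± 0.16 but Inha at −1.50 ± 0.24. Hormone receptor genes were higher in 19 of 26 cases and lower in 3 (20 and 3 adjusted over the list alone, camera adjusted p = 0.00131). Adcyap1r1, a neuropeptide receptor gene, was at 3.31 ± 0.42 and the prolactin receptor gene Prlr at −2.27 ± 0.20.

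Other lists were called for stem-like cells with the preset correlation alone. Retinoic acid genes were higher in 7 of 10 cases and lower in 1 (7 and 1 adjusted over the list alone, camera adjusted p = 0.00369, adjusted p = 0.0903 with an estimated correlation). The binding protein gene Crabp2 was at 6.36 ± 0.33 and Dhrs3 at 5.78 ± 0.36. Hedgehog genes were higher in 6 of 8 cases (6 adjusted over the list alone, camera adjusted p = 0.00161, adjusted p = 0.111 with an estimated correlation). Of 22 pituitary transcription factors 13 were higher and 2 lower (13 and 2 adjusted over the list alone, camera adjusted p = 0.00163, adjusted p = 0.0876 with an estimated correlation). Isl1 was at 4.27 ± 0.16, Tcf7l2 at 3.51 ± 0.16 and Insm1 at −1.23 ± 0.16. Immediate early and heat shock genes were higher in 18 of 19 cases (18 adjusted over the list alone, camera adjusted p = 2.39e-08, adjusted p = 0.111 with an estimated correlation). Atf3 was at 2.66 ± 0.12 and Egr1 at 2.07 ± 0.17. The tissue had been digested for 4 h before capture. Interferon and antigen presentation genes were higher in 17 of 18 cases (17 adjusted over the list alone, camera adjusted p = 7.57e-07, adjusted p = 0.169 with an estimated correlation). H2-K1 was at 2.81 ± 0.07 and Bst2 at 3.61 ± 0.13. Matrix genes were higher in 12 of 19 cases (12 adjusted over the list alone, camera adjusted p = 0.000974, adjusted p = 0.159 with an estimated correlation). Genes of neuropeptides and secreted factors were higher in 12 of 18 and lower in 1 (12 and 2 adjusted over the list alone, camera adjusted p = 0.0162, adjusted p = 0.0903 with an estimated correlation). Igfbp5 was at 6.78 ± 0.09. Endoplasmic reticulum folding genes were lower in 13 of 18 cases and higher in 2 (14 and 3 adjusted over the list alone, camera adjusted p = 0.000189, adjusted p = 0.123 with an estimated correlation). Mitochondrially encoded genes were lower in 10 of 13 (10 adjusted over the list alone, camera adjusted p = 0.000192, adjusted p = 0.232 with an estimated correlation). In all, 3839 genes were higher and 3191 lower of 12166 tested, and 779 genes of at least 50 CPM differed at least 2-fold in mean CPM, a count made without the test. A share of 6.38 ± 2.63% of stem-like cells had over 30% Gh UMIs.

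Somatotrope-like cells were set apart from the other hormone classes by Ppp1r14a, an inhibitor of myosin phosphatase, at 167 ± 18.2 CPM against 8.63 (4.29 ± 0.08, adjusted p = 4e-70). The metalloproteinase gene Pappa2 was at 85.0 ± 14.0 CPM (5.04 ± 0.15). The retinoid receptor gene Rxrg was at 80.7 ± 8.51 CPM (5.10 ± 0.28, adjusted p = 6.95e-09), Atg9b at 62.1 ± 3.18 CPM (4.63) and Car10 at 57.2 ± 5.08 CPM (4.92 ± 0.18). Outside the hormone classes Ppp1r14a was also at 281 CPM in fibroblast-like cells. Of 15 calcium and sodium channel genes 9 were lower and 2 higher (9 and 2 adjusted over the list alone, camera adjusted p = 0.00664, adjusted p = 0.12 with an estimated correlation). Scn2a1 was at −3.32 ± 0.33 and Scn8a at 1.25 ± 0.12. Mesenchymal genes were lower in 4 of 14 cases and higher in 1 (4 and 1 adjusted over the list alone, camera adjusted p = 0.0493, adjusted p = 0.131 with an estimated correlation). Secretory granule genes were lower in 14 of 25 cases and higher in 4 (14 and 4 adjusted over the list alone, camera adjusted p = 0.0016, adjusted p = 0.178 with an estimated correlation). Chga was at −2.95 ± 0.25 and Sytl4 at 1.59 ± 0.06. Folding genes were higher in 10 of 18 and lower in 2 (10 and 2 adjusted over the list alone, camera adjusted p = 0.00742, adjusted p = 0.281 with an estimated correlation). Ddit3 was at 1.01 ± 0.08. In total 3182 genes were higher and 2386 lower, and 240 differed at least 2-fold. With DESeq2 the split was 2238 higher and 2660 lower, with the median of all genes shifted by −0.11.

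Lactotrope-like cells had 83.8 ± 2.57 CPM of Angpt1, an angiopoietin ligand gene, against 2.36 in the other hormone classes (5.61 ± 0.16, adjusted p = 4.38e-55). Hepacam2 was at 188 ± 4.52 CPM, Asb4 at 181 ± 7.36 CPM, Edil3 at 109 ± 7.36 CPM and Ramp1, which encodes a partner of the calcitonin receptor-like receptor, at 151 ± 0.955 CPM (4.03 ± 0.21, adjusted p = 1.87e-08). Ramp1 also stood at 174 CPM in macrophage-like and 102 CPM in stem-like cells. Folding genes were higher in 11 of 18 cases and lower in 2 (11 and 2 adjusted over the list alone, camera adjusted p = 3.19e-05, adjusted p = 0.13 with an estimated correlation). Sdf2l1 was at 1.32 ± 0.07 and Manf at 1.30 ± 0.06. Of 16 potassium channel genes 11 were lower and 1 higher (11 and 2 adjusted over the list alone, camera adjusted p = 0.00514, adjusted p = 0.109 with an estimated correlation). Kcnk3 was at −5.17 ± 0.40 and Kcnd3 at 2.85 ± 0.26. Genes of the BMP, FGF and TGF-beta list were lower in 12 of 24 cases and higher in 2 (12 and 2 adjusted over the list alone, camera adjusted p = 0.00374, adjusted p = 0.0529 with an estimated correlation). Altogether 2790 genes were higher and 2282 lower, and 207 differed at least 2-fold. The split was 1990 higher and 3106 lower with totals that left out the hormone genes, and 1986 and 2544 with DESeq2. The median of all genes shifted by −0.12 and −0.10.

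Gonadotrope-like cells expressed Tgfbr3l, a gene related to the TGF-beta co-receptor (chromosome 8, 4248214 to 4251423), at 4145 ± 210 CPM against 13.2 CPM in the other hormone classes (8.35 ± 0.20, adjusted p = 1.45e-11). Spp1, which encodes osteopontin, was at 1938 ± 154 CPM against 5.38 (8.81 ± 0.30, adjusted p = 4.09e-10), and was also at 736 CPM in fibroblast-like and 84.5 CPM in stem-like cells. The BMP antagonist gene Grem1 was at 84.3 ± 8.20 CPM, 288-fold higher, and the sulfotransferase gene Sult5a1 at 85.0 ± 6.16 CPM, 184-fold higher. Speer4e, at 126 ± 8.10 CPM, belongs to a family of near-identical genes and is uncertain, and its adjusted p was 0.0894 with DESeq2. Of 22 pituitary transcription factors 11 were higher and 6 lower (12 and 6 adjusted over the list alone, camera adjusted p = 0.0269, adjusted p = 0.146 with an estimated correlation). Nr0b1 was at 6.62 ± 0.21, Isl1 at 5.02 ± 0.18, Gata2 at 4.94 ± 0.17 and Etv1 at −3.87 ± 0.30. Secretory granule genes were higher in 15 of 25 cases and lower in 5 (15 and 5 adjusted over the list alone, camera adjusted p = 0.000737, adjusted p = 0.146 with an estimated correlation). The largest were Scg2 (3.70 ± 0.17) and Chga (3.44 ± 0.18). Mitochondrially encoded genes were higher in 12 of 13 cases (12 adjusted over the list alone, camera adjusted p = 5.57e-17). Their median share of UMIs per cell was 7.07 ± 0.218%, against 1.87 ± 0.0200% in somatotrope-like cells. It was 2.805 ± 0.162% in lactotrope-like, 4.33 ± 0.455% in melanotrope-like and 5.18 ± 0.075% in corticotrope-like cells. These are shares of all UMIs, and Gh took a median of 62.0 ± 0.473% of them in somatotrope-like cells. Prl took 31.9 ± 2.37% in lactotrope-like cells, so in both classes hormone transcripts lower the mitochondrial share. There were 2458 genes higher and 1919 lower, and 280 passed the 2-fold count.

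Corticotrope-like cells carried transcripts of Tnnt1 and Tnni3, which encode troponin subunits known from striated muscle. Tnnt1 was at 270 ± 30.8 CPM against 1.37 in the other hormone classes (8.25 ± 0.19, adjusted p = 5.1e-29) and Tnni3 at 63.99 ± 3.85 CPM, 237-fold higher. The 2 genes are neighbours on the minus strand of chromosome 7 (4504570 to 4516382 and 4518305 to 4524229). Acbd7 was at 81.7 ± 4.18 CPM, and the immediate early gene Egr4 at 104 ± 20.1 CPM (5.60 ± 0.40, adjusted p = 8.02e-06). Immediate early and heat shock genes were higher in 18 of 19 cases (18 adjusted over the list alone, camera adjusted p = 2.64e-21). Atf3 was at 3.16 ± 0.14, Fosb at 2.84 ± 0.18 and Junb at 2.72 ± 0.23. Of 22 pituitary transcription factors 10 were higher and 4 lower (12 and 4 adjusted over the list alone, camera adjusted p = 0.00615, adjusted p = 0.102 with an estimated correlation). Neurod1 was at 4.88 ± 0.26. Folding genes were lower in 11 of 18 cases and higher in 4 (13 and 4 adjusted over the list alone, camera adjusted p = 5.75e-05, adjusted p = 0.13 with an estimated correlation). Creld2 was at −1.48 ± 0.14 but Ddit3 at 1.65 ± 0.10. Of the tested genes 1880 were higher and 1538 lower, and 337 passed the 2-fold count. The median mitochondrial share was 5.18 ± 0.0750% of UMIs.

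Melanotrope-like cells expressed S100a16, a calcium-binding protein gene, at 114 ± 16.6 CPM (5.09 ± 0.19 over the other hormone classes), although it was higher still in endothelial-like (390 CPM) and stem-like cells (243 CPM). Slitrk6 was at 77.7 ± 10.0 CPM (6.46 ± 0.28) and at 59.3 CPM in stem-like cells, Megf11 at 83.8 ± 17.2 CPM, and Gulo, the last enzyme of vitamin C synthesis, at 50.2 ± 1.18 CPM, 95.3-fold higher. Crisp1, at 94.9 ± 3.55 CPM (adjusted p = 2.4e-05), has close paralogs and is uncertain. Of 15 calcium and sodium channel genes 8 were higher (8 adjusted over the list alone, camera adjusted p = 0.00149, adjusted p = 0.0903 with an estimated correlation). Scn2a1 was at 5.17 ± 0.25. Cyclic nucleotide signalling genes were higher in 9 of 23 cases (9 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.00489, adjusted p = 0.0567 with an estimated correlation), and the kinase inhibitor gene Pkib was at 5.73 ± 0.17. Immediate early and heat shock genes were lower in 14 of 19 cases (15 adjusted over the list alone, camera adjusted p = 4.29e-11, adjusted p = 0.102 with an estimated correlation). The counts were 1269 higher and 977 lower, and 258 were at least 2-fold apart. The split was 1550 and 608 with DESeq2, where the median of all genes shifted by 0.12.

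**Figure D2:**
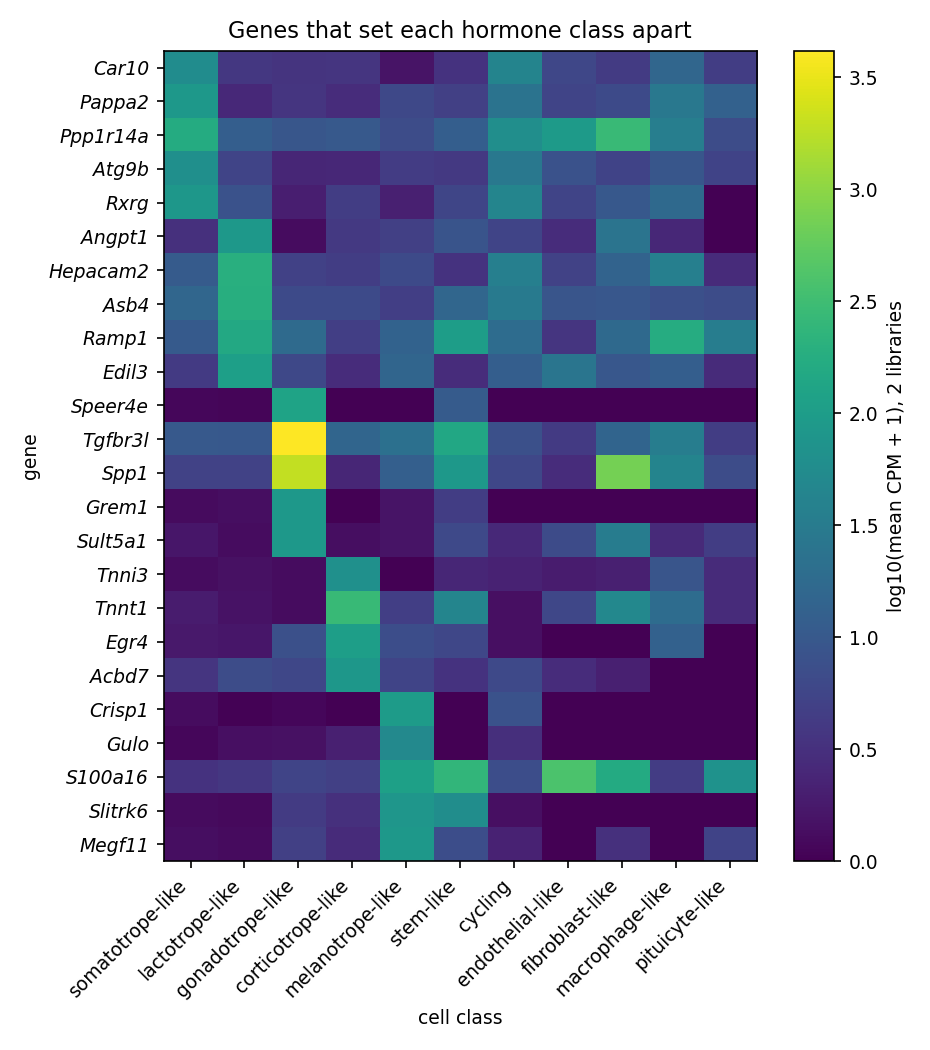
Mean expression over 2 libraries, as log10 of CPM + 1, of genes that most set apart each of the 5 hormone classes, in the 11 classes tested. Tgfbr3l reached 4145 CPM in gonadotrope-like cells, and some genes such as Spp1 and S100a16 were also high outside the hormone classes.

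Melanotrope-like and corticotrope-like cells both express Pomc, at 482300 ± 5700 and 61820 ± 1070 CPM, and were compared directly. Higher in melanotrope-like cells were Lgals1, which encodes a galectin, at 467 ± 121 CPM against 16.9 (4.75 ± 0.22, adjusted p = 2.92e-16), and the junction gene Jam2 at 79.3 ± 1.56 CPM (5.71 ± 0.44). The lipase gene Lpl was at 73.4 ± 10.0 CPM (5.59) and Enc1 at 70.3 ± 16.4 CPM (112 UMIs against 2). Gulo, Megf11, Slitrk6 and S100a16 lay between 5.47 and 4.91. Crisp1 had 154 UMIs against 0 and was at least 85.3-fold higher, taking 3 counts over the group as the floor (adjusted p = 0.0014, 0.0515 with DESeq2). Gal, the galanin gene, averaged 437 ± 604 CPM, but its log2 fold change was 8.26 in library 1 and 1.74 in library 2. Lower in melanotrope-like cells were Tnnt1 at 3.75 CPM against 270 (−6.23 ± 0.36, adjusted p = 2.18e-16) and Tnni3 with 0 UMIs against 172 (at least 34.7-fold). So were the clock-related gene Ciart with 2 UMIs against 224, Rprml with 1 against 146 and Neurod1 with 2 against 140. The cell cycle inhibitor gene Cdkn1a was at 6.08 CPM against 153 (−4.65 ± 0.30). Fosb was at 12.6 ± 9.84 CPM against 277 ± 107 (−4.39 ± 0.40, adjusted p = 7.9e-06). Maff, Slc5a3 and Acbd7 lay between −4.53 and −4.24. With 22 cells per class and library, the adjusted p of Acbd7 was 0.0548.

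Immediate early and heat shock genes were lower in melanotrope-like than in corticotrope-like cells in 16 of 19 cases (16 adjusted over the list alone, camera adjusted p = 1.05e-22). Atf3 was at −3.88 ± 0.26, Dnajb1 at −3.85 ± 0.36 and Junb at −3.66 ± 0.40. Junb was found, without thinning, in 86.9% and 90% of corticotrope-like cells of libraries 1 and 2, in 21.9% and 60.1% of melanotrope-like cells and in 51.9% and 55.1% of endothelial-like cells, at median depths of 4353, 6650 and 4538 UMIs. Folding genes were higher in 12 of 18 cases and lower in 4 (13 and 4 adjusted over the list alone, camera adjusted p = 0.000974, adjusted p = 0.203 with an estimated correlation). Secretory granule genes were higher in 10 of 25 and lower in 2 (11 and 3 adjusted over the list alone, camera adjusted p = 0.00205, adjusted p = 0.174 with an estimated correlation). Chga was at 2.85 ± 0.31 and Rab3b at −1.52 ± 0.14. The comparison gave 1204 genes higher and 1178 lower, and 426 passed the 2-fold count.

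**Figure D3:**
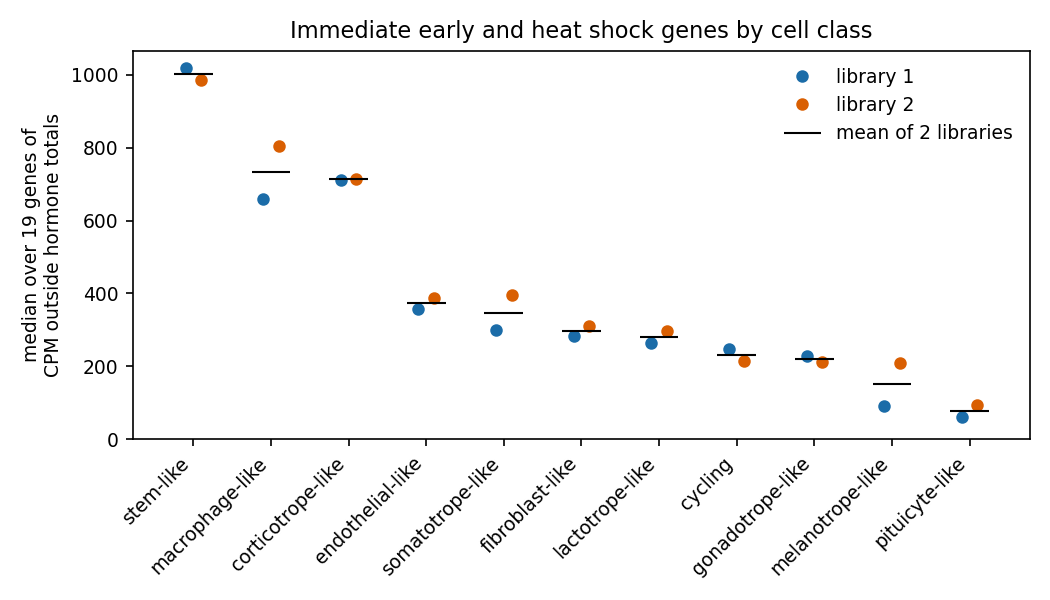
Median over 19 immediate early and heat shock genes of their CPM outside the hormone totals, per class, with a point per library and a line at the mean of the 2 libraries. Stem-like cells stood at 1018 and 987, corticotrope-like cells at 712 and 715, and melanotrope-like cells at 92.0 and 209.6.

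Lactotrope-like and somatotrope-like cells both depend on the transcription factor Pou1f1 and were compared with each other. Angpt1 was at 83.8 ± 2.57 CPM in lactotrope-like cells against 2.19 (5.25 ± 0.15, adjusted p = 3.22e-55), and Edil3 was higher by 5.13 ± 0.14. Further genes higher in lactotrope-like cells were Ecel1 (4.75), Cd24a (4.60), Lgals1 (4.52), Qpct (4.26), Hepacam2 (4.24), Asic4 (4.07) and Ramp1 (3.98). Lower in lactotrope-like cells were the glucocorticoid receptor gene Nr3c1, at 2.53 CPM against 53.4 (−4.37 ± 0.16, adjusted p = 1.05e-45), and Cidea, which encodes a lipid droplet protein, at 5.44 CPM against 194 ± 54.3 (−5.14 ± 0.24, adjusted p = 6.18e-09). Ceacam10 was at 1.89 CPM against 104 (−5.77 ± 0.17) but belongs to a multigene family and is uncertain. Pappa2 (−5.67), Arhgap36 (−5.33), the ligand gene Wnt10a (−4.68), Car10 (−4.26), Cyr61 (−4.00 ± 0.44), Sms (−3.93) and Ppp1r14a (−3.92) were lower as well. Of 16 potassium channel genes 9 were lower and 3 higher (9 and 3 adjusted over the list alone, camera adjusted p = 0.0187, adjusted p = 0.128 with an estimated correlation). Kcnmb4 was at −3.04 ± 0.14 and Kcnd3 at 1.54 ± 0.17. Interferon and antigen presentation genes were lower in 10 of 18 cases and higher in 2 (14 and 2 adjusted over the list alone, camera adjusted p = 0.0161, adjusted p = 0.44 with an estimated correlation). Psmb8 was at −2.08 ± 0.09. There were 2606 genes higher and 2875 lower in lactotrope-like cells, and 244 were at least 2-fold apart. The split was 2126 and 3788 with totals that left out the hormone genes. With 22 cells per class and library, adjusted p was 0.0561 for Ecel1, 0.269 for Cd24a, 0.295 for Lgals1 and 0.0954 for Cyr61.

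Thyrotrope-like cells, with 10 and 31 cells per library, were too few for the planned test, so a fit with this class added was chosen after the data were seen. Their Tshb level was 102700 ± 17300 CPM. Prss28, a serine protease gene, was at 591 ± 12.5 CPM against 3.01 in the other hormone classes (196-fold, adjusted p = 9.09e-45), and Ttr, which encodes the thyroid hormone carrier transthyretin, at 129 ± 5.36 CPM against 3.10 (41.7-fold, adjusted p = 9.53e-26). Slc10a4 was at 122 ± 42.0 CPM, Col24a1 at 62.1 ± 15.5 CPM and Chrdl1 at 59.5 ± 11.8 CPM. Against gonadotrope-like cells, which share the Cga subunit, thyrotrope-like cells had 362 ± 63.8 CPM of the surface protein gene Thy1 against 7.52 (5.71 ± 0.30, adjusted p = 2.07e-19). They also had 82.7 ± 15.8 CPM of the glypican gene Gpc6, 70.01 ± 41.2 of Nell2 and 57.1 ± 37.4 of Spink8. Cited1 was at 62.6 ± 88.6 CPM, with log2 fold changes of 0.79 in library 1 and 5.62 in library 2. Genes with 0 UMIs in thyrotrope-like cells were lower than in gonadotrope-like cells by at least 16.7-fold for the exchange factor gene Rasgrf1, 12.5-fold for Anxa2, 8.17-fold for Sult5a1, 7.11-fold for Espn, and 7.06-fold for Foxp2. For Dgkk the bound was 7.04-fold, and it was 6.73-fold for Spock1, 6.48-fold for C1ql2 and 5.54-fold for Chst8. Speer4e was lower by at least 12.1-fold, with adjusted p = 0.731 in DESeq2.

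Of 12270 genes tested with thyrotrope-like cells added, 247 were higher and 296 lower than in the other hormone classes, and 336 higher and 651 lower than in gonadotrope-like cells. These splits moved with the scaling. Against the other hormone classes they were 329 and 142 with DESeq2 size factors in edgeR, 282 and 197 with totals that left out the hormone genes and 518 and 96 with DESeq2. Under the same settings they were 431 and 414, 385 and 483, and 603 and 258 against gonadotrope-like cells. The median of all genes shifted by 0.18 with the size factors in both comparisons, by 0.11 with the hormone-free totals against gonadotrope-like cells, and by 0.46 and 0.34 with DESeq2. At least 2-fold apart were 342 and 556 genes, against 422 and 634 in library 2 alone and 606 and 798 in library 1 alone, which has 10 of the cells. Mitochondrially encoded genes were higher than in the other hormone classes in 10 of 13 cases (12 adjusted over the list alone, camera adjusted p = 1.14e-07, adjusted p = 0.152 with an estimated correlation), and their median share was 9.41 ± 3.70% of UMIs. Heat shock and immediate early genes were lower in 2 of 19 cases (3 adjusted over the list alone, camera adjusted p = 0.000281, adjusted p = 0.225 with an estimated correlation). Another 8 lists (Notch, Wnt, hedgehog, BMP with FGF and TGF-beta, retinoic acid, mesenchymal, matrix and G2/M genes) were called upward by camera although the median and the mean of their log2 fold changes were below 0. At most 1 member of each passed the test in either direction, over all genes and adjusted over the list alone. Their adjusted p ranged from 5.07e-05 to 0.0137, and from 0.0567 to 0.268 with an estimated correlation. Camera compares a list with the remaining genes and not with 0. The median log2 fold change of all tested genes was −0.37 against the other hormone classes and −0.34 against gonadotrope-like cells. Against gonadotrope-like cells, Wnt (2 higher and 1 lower of 22, the same adjusted over the list alone, camera adjusted p = 0.0403) and mesenchymal genes (1 higher of 14, 1 adjusted over the list alone, camera adjusted p = 0.00196) were called upward with a median and mean below 0. G2/M genes (0 of 20 past the test, 0 adjusted over the list alone, camera adjusted p = 1.81e-06) had a mean below 0 and a median above it. For these 3 lists the adjusted p with an estimated correlation was 0.169, 0.0923 and 0.213.

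Cycling cells expressed the spindle and mitosis genes Ube2c (627 ± 17.0 CPM against 1.05 in the hormone classes, adjusted p = 1.18e-11), Spc25 (443 ± 50.9 CPM against 0.626) and Cenpf (362 ± 2.36 CPM, 427-fold, adjusted p = 2.97e-65). Ccnb2 (215 ± 9.93 CPM), Prc1 (198 ± 5.25 CPM), Hmmr (152 ± 4.10 CPM), Fam64a (133 ± 34.5 CPM), Ckap2l (122 ± 4.69 CPM), Aurkb (83.1 ± 4.09 CPM) and the DNA glycosylase gene Neil3 (52.9 ± 14.0 CPM) were higher too. All 20 genes of the G2/M list (20 adjusted over the list alone, camera adjusted p = 1.21e-32) and 18 of 19 S phase genes (18 adjusted over the list alone, camera adjusted p = 3.97e-22) were higher. Rrm2 was at 8.13 ± 0.24. The class was defined by other genes of the cell cycle, so these lists are not independent of its name. Lower were the metallothionein gene Mt3 (−2.12 ± 0.16, adjusted p = 1.34e-21), Hdac11 (−2.38), Otub1 (−2.06), Pabpc1l (−3.32 ± 0.47) and Tgfbr3l (−2.61 ± 0.70, adjusted p = 0.013), whose hormone-class mean of 839.5 CPM came from gonadotrope-like cells. With 22 cells per class and library the adjusted p of Pabpc1l was 1 and that of Tgfbr3l 0.488. Secretory granule genes were lower in 16 of 25 cases and higher in 1 (16 and 1 adjusted over the list alone, camera adjusted p = 9.81e-06, adjusted p = 0.0876 with an estimated correlation). Mitochondrially encoded genes were lower in 11 of 13 (11 adjusted over the list alone, camera adjusted p = 1.25e-11, adjusted p = 0.0763 with an estimated correlation). The median mitochondrial share was 1.855 ± 0.082% of UMIs in cycling cells and 1.873 ± 0.02% in somatotrope-like cells. Gh took a median of 51.6 ± 0.992% and 62.0 ± 0.473% of all UMIs in these classes, which lowers both shares. The counts were 2380 higher and 1994 lower, and 509 were at least 2-fold apart. The split was 2806 and 1449 with totals that left out the hormone genes, where the median of all genes shifted by 0.12. Of 109 cycling cells in library 1 and 102 in library 2, 81 (74.3%, exact 95% interval 65.1 to 82.2) and 79 (77.5%, 68.1 to 85.1) had over 30% Gh UMIs, against 58.8% and 54.3% of the cells of the hormone classes. The cycling cluster, with 75.8% high-Gh cells over both libraries, was exempt from the rule on mixed clusters, which would have left it unnamed.

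Endothelial-like cells were compared with the mean of all other classes. Myct1, at 87.5 ± 11.8 CPM against 0.0439, the transcription factor gene Sox17 at 72.8 ± 4.02 CPM and the multimerin gene Mmrn1 at 92.0 ± 0.794 CPM were the highest by the fixed rule. Matrix genes were higher in 15 of 19 cases (15 adjusted over the list alone, camera adjusted p = 1.86e-08), such as the collagen gene Col4a1 (6.84 ± 0.17). Secretory granule genes were lower in 21 of 25 (21 adjusted over the list alone, camera adjusted p = 8.44e-09). Hippo genes were higher in 11 of 16 cases and lower in 2 (11 and 2 adjusted over the list alone, camera adjusted p = 0.000974). Ctgf was at 5.52 ± 0.32. Notch genes were higher in 11 of 19 and lower in 2 (11 and 2 adjusted over the list alone, camera adjusted p = 0.00286, adjusted p = 0.0657 with an estimated correlation), with the ligand gene Dll4 at 7.36 ± 0.44. Interferon and antigen presentation genes were higher in 18 of 18 cases (18 adjusted over the list alone, camera adjusted p = 2.42e-13, adjusted p = 0.0813 with an estimated correlation). B2m was at 3.75 ± 0.10. G2/M genes were higher in 20 of 20 cases (20 adjusted over the list alone, camera adjusted p = 2.34e-06, adjusted p = 0.219 with an estimated correlation). That is against a mean of log2 levels over all other classes, and not against each class. In cycling cells the cell cycle marker Top2a was at 320 ± 28.5 CPM, against 25.5 ± 1.25 CPM in endothelial-like cells. The comparison gave 3096 genes higher and 2202 lower, and 1100 were at least 2-fold apart. A share of 9.22 ± 3.41% of endothelial-like cells had over 30% Gh UMIs. The adjusted p of Sox17 was 0.145 with DESeq2.

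Fibroblast-like cells had 823 ± 116 CPM of the dipeptidase gene Dpep1 against 1.38 in all other classes, 234 ± 9.38 CPM of the transcription factor gene Tcf21 and 125 ± 21 CPM of the alcohol dehydrogenase gene Adh1. Matrix genes were higher in 17 of 19 cases (17 higher and 1 lower adjusted over the list alone, camera adjusted p = 3e-22). Bgn was at 8.99 ± 0.11. Mesenchymal genes were higher in 11 of 14 cases and lower in 1 (12 and 1 adjusted over the list alone, camera adjusted p = 6.93e-09). Sparc was at 5.95 ± 0.16. Markers of pericytes were in this class too, with Rgs5 at 747.8 ± 108 CPM, Tagln at 540.5 ± 11.3 CPM and Pdgfrb at 324.5 ± 30.7 CPM. Retinoic acid genes were higher in 10 of 10 cases (10 adjusted over the list alone, camera adjusted p = 1.04e-08). Rarres2 was at 9.28 ± 0.18. Genes of neuropeptides and secreted factors were higher in 9 of 18 cases (11 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.000129). Igfbp2 was at 8.25 ± 0.14. The counts were 2067 higher and 1083 lower, and 794 were at least 2-fold apart. The split was 2283 and 725 with DESeq2, where the adjusted p of Adh1 was 0.147.

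Macrophage-like cells expressed Trem2, a receptor gene of microglia and macrophages, at 781 ± 162 CPM against 0.487, Adgre1, which encodes the antigen F4/80, at 437 ± 157 CPM and Cd48 at 249 ± 83.1 CPM. A share of 16.1% of these cells in library 1 and 6.02% in library 2 had over 30% Gh UMIs. Interferon and antigen presentation genes were higher in 18 of 18 cases (18 adjusted over the list alone, camera adjusted p = 1.51e-19). Cd74 was at 10.48 ± 0.40. Of 19 immediate early and heat shock genes 16 were higher (17 adjusted over the list alone, camera adjusted p = 2.09e-11, adjusted p = 0.111 with an estimated correlation). Zfp36 was at 3.72 ± 0.15. There were 1877 genes higher and 826 lower, and 983 were at least 2-fold apart. The split was 1269 and 3387 with totals that left out the hormone genes, where the median of all genes shifted by −0.60, and 2026 and 436 with DESeq2, where it shifted by 0.11. With DESeq2, adjusted p was 0.106 for Adgre1 and 0.132 for Cd48.

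Pituicyte-like cells, with 22 and 33 cells per library, had 364 ± 105 CPM of the synaptic adhesion gene Lrrtm3, 294 ± 50.8 CPM of Fndc3c1 and 262.5 ± 53.3 CPM of the carbonic anhydrase gene Car14. Wnt genes were higher in 12 of 21 cases (13 higher and 1 lower adjusted over the list alone, camera adjusted p = 3.23e-06). Fzd5 was at 4.38 ± 0.33 and Lgr4 at 3.37 ± 0.33. Secretory granule genes were lower in 16 of 25 (19 adjusted over the list alone, camera adjusted p = 3.46e-10). Cyclic nucleotide signalling genes were lower in 7 of 23 cases (8 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.00267). Gnas was at −2.10 ± 0.08. The 19 immediate early and heat shock genes were lower in 16 cases (17 adjusted over the list alone, camera adjusted p = 6.81e-09, adjusted p = 0.142 with an estimated correlation). Mitochondrially encoded genes were higher in 11 of 13 (11 adjusted over the list alone, camera adjusted p = 2.08e-11, adjusted p = 0.0743 with an estimated correlation). The median mitochondrial share was 10.7 ± 0.260% of UMIs. The counts were 1159 higher and 851 lower, and 705 were at least 2-fold apart. The split was 1500 and 437 with totals that left out the hormone genes and 1524 and 438 with DESeq2. The median of all genes shifted by 0.26 and 0.23, and by 0.13 with DESeq2 size factors in edgeR. With DESeq2 the adjusted p was 0.124 for Lrrtm3 and 0.0795 for Fndc3c1.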

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

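Both items were picked after the data were seen, and no test of a cause was run on either. The 45 barcodes with under 250 genes lie outside the cells used, and a median of 95.2% of their UMIs came from haemoglobin genes. An unnamed cluster of 368 cells was led by Tshb, with a Tshb UMI in 53.0% of its cells against 26.6% of somatotrope-like cells, without thinning, at a median depth of 12632.5 UMIs in the cluster. Of these cells 83.4% had over 30% Gh UMIs and 71 held at least 10 Tshb UMIs. The cluster matched the thyrotrope-like markers best, with 5 of them, and went unnamed for its mix of high-Gh and other cells. The 41 thyrotrope-like cells found at resolution 2 came from the unnamed cells, and how many of them lay in this cluster was not counted.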

How the results depend on the processing

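The added settings, chosen after the data were seen, were another Leiden seed, the thyrotrope-like fit, the changed 2-fold count, and the fit without high-Gh cells. The share of named cells was 91.8% and became 86.0% with doublet calls kept and 100% on variable genes. It was 78.8% at resolution 0.5, 80.1% at resolution 2 and 90.5% with another Leiden seed. At resolution 0.5 a cluster of 1147 cells, 92.85% of them high in Gh, matched the somatotrope-like class best. It stayed unnamed because only 2 markers were above the midpoint, under the minimum of 3. Causes of these changes were not otherwise tested. With 22 cells per class and library and 4823 genes tested, fewer cells and genes left 1737 calls for stem-like, 351 somatotrope-like, 286 lactotrope-like, 545 gonadotrope-like, 402 corticotrope-like, 234 melanotrope-like, 832 cycling, 1509 endothelial-like, 1006 fibroblast-like, 1032 macrophage-like and 1033 pituicyte-like cells, 284 for melanotrope-like against corticotrope-like and 144 for lactotrope-like against somatotrope-like cells. Totals without hormone genes gave 4656 calls for macrophage-like cells, against 2703; the cause was not tested. With no replicate block, no count moved by over 1.5 times, as in the 6904 calls for stem-like cells against 7030. Leaving out each library in turn gave 422 to 606 genes at least 2-fold apart for thyrotrope-like cells, against 342, since fewer cells remain, and moved no other such count by over 1.5 times. With an estimated correlation 26 of 286 list tests passed, against 110. Tshb was detected in 4.94% of somatotrope-like cells thinned to 2000 UMIs and in 26.6% without thinning, against 2.62%, as depth rose. Of 179 alternatives to the 15 counts, 165 stayed within 1.5 times. Of 1714 alternatives to 137 named-gene results, 1697 were labelled the same, 17 lost their call (10 with DESeq2, 7 with equal cells) and 0 reversed. The 1697 include 137 results for each library left out. These carry no adjusted p, and the named-gene rule and the label left them no other outcome. A gene that dropped out of a fit was not counted, so equal cells gave 79 kept and 7 lost calls, where another Leiden seed gave 112 kept. A minimum of 1500 UMIs removed no cell, and thyrotrope-like cells gave no test under the alternatives on cells. At resolution 0.5 no class was named macrophage-like. A cluster of 327 cells with 7 macrophage markers formed there, but 58.4% of its cells were high in Gh. The rule on mixed clusters left it unnamed. In simulated lactotrope-like against somatotrope-like cells 34% of 2-fold changes were recovered, and depth was not varied there.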

Other observations

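All comparisons in this part were chosen after the data were seen, as were the patterns to be explained and the limit of 30% Gh UMIs. Of the 8 tests of explanations, 5 had their predictions written before the test itself. For the free RNA tests for stem-like and for cycling cells and for the random draw they were written afterwards. Cycling cells with over 30% Gh UMIs were compared with somatotrope-like cells, and 1444 genes were higher and 1681 lower of 12157 tested. The somatotrope-like side includes the cluster of 300 cells with Cdk1 among its leading genes. Apart from mitosis genes such as Ube2c (642 ± 41.1 CPM against 1.51), the lower genes included the cathepsin gene Ctsl at 56.8 ± 13.6 CPM against 271 ± 19.7 (−2.25 ± 0.14, adjusted p = 3.58e-29), the collagen chaperone gene Serpinh1 at 84.6 ± 10.4 against 320 ± 93.1, Dapl1 at 148 ± 12.7 against 507 ± 57.1, and the glutathione peroxidase gene Gpx1 at 31.1 ± 4.57 against 117 ± 0.902. Cells with high Prl but not high Gh made up 15.6% of cycling cells in library 1 and 13.7% in library 2, against 23.3% and 26.0% of the cells of the hormone classes.

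Without thinning, Tnnt1 was detected in 49.2% and 47.2% of corticotrope-like cells of libraries 1 and 2, in 1.90% and 0.725% of melanotrope-like cells and in 1.55% and 3.40% of endothelial-like cells, at median depths of 4353, 6650 and 4538 UMIs. The immediate early gene Npas4 was detected in 43.7% and 47.2% of corticotrope-like cells, 4.76% and 14.5% of melanotrope-like cells and 0.775% and 2.04% of endothelial-like cells. Gal in melanotrope-like cells came from 9 of 105 cells in library 1, where a single cell held 364 of 612 UMIs, and from 6 of 138 cells with 9 UMIs in library 2. Cells with over 30% Gh and over 15% Prl UMIs numbered 13 in library 1 and 3 in library 2 among those used, and 7 and 15 among the doublet calls.

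Stem-like cells held transcripts of gonadotrope hormones: outside the hormone totals, Fshb was 70.1 and 53.0 times its endothelial-like level in libraries 1 and 2, while Gh was 0.609 and 0.568 times its level there. Free RNA keeps its genes in 1 ratio in every class, so these values argue against it. The 50 genes most specific to gonadotrope-like cells stood in stem-like cells at a median of 5.53% and 5.85% of their gonadotrope-like level, which is 2.31 and 1.35 times the percentage for Lhb (mean 1.83), where a range of 0.5 to 2 in both libraries was set beforehand for gonadotrope-like cells in the same droplets or clusters. Library 1 lay above it, so such cells remain a candidate source and are neither shown nor excluded. The percentages were 5.83% and 5.25% for Fshb, 2.96% and 4.45% for Cga and 2.39% and 4.34% for Lhb, so Fshb lay near the median of the 50 genes. Those genes were chosen without regard to stem-like cells, so any that stem-like cells express themselves raise the median. Tgfbr3l at 2.96% and 4.53% and Spp1 at 2.99% and 6.00% of their gonadotrope-like level belong to the same pattern. At a Leiden resolution of 2 2 clusters matched the stem cell markers best, with 193 and 167 cells and median depths of 7288 and 10453 UMIs, and of these the latter had Lhb and Cga among its 10 leading genes. The design has no group that bears on a biological explanation, and none was tested.

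More than 70% of cycling cells had over 30% Gh UMIs. Of endothelial-like cells, which should lack Gh, 9.22 ± 3.41% did, and free RNA gives all classes a like low share, which argues against it. The median Gh share of cycling cells was 43.4 and 58.6 times the endothelial-like one, which follows from the pattern itself and adds no evidence. In droplets that hold a somatotrope-like cell and a dividing cell of another class, genes specific to the other classes should appear, but their medians, less the somatotrope-like level, were below 0 in every other class except lactotrope-like cells in library 1. With values below 0 taken as 0 they summed to 0.308% and 0% of their own levels in libraries 1 and 2. The lower interval bounds lay 6.23 and 13.8 points above the share in the hormone classes, which argues against a random draw of their cells. As a hypothesis, found and tested on the same data, dividing cells in these glands may be of the growth hormone class more often than the hormone classes as a whole. The design has no group to test a biological explanation.

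Immediate early and heat shock genes were higher in corticotrope-like cells, with a median log2 fold change of 1.84 over the list. With totals that left out the hormone genes it was 1.90, so the counts taken by hormone genes do not account for it. For macrophage-like cells mixed in to account for it, the excess over the other hormone classes would need 89.2% and 72.8% of the macrophage-like level in libraries 1 and 2. Genes specific to macrophages had an excess of −0.0329% and −0.0203% of their macrophage-like level, a ratio of −0.0004 and −0.0003. A response to the digestion cannot be told apart, since 0 libraries were made without digestion, and it may act differently on each class. No biological explanation was tested, as the design gives no group for it.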
